A study of Mus musculus with 9 samples.

How the data were processed

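Gene expression was measured on 9 Affymetrix Mouse Gene 1.0 ST arrays from immortalized mouse embryonic fibroblasts of an ICR background. Per the labels, cells took up an adenovirus carrying a short hairpin RNA (shRNA) at 1e8 pfu per ml for 2 h and were grown for a further 70 h at 37 degrees in medium with 10% serum, and 200 ng of RNA was labelled. The shRNA was a scrambled control, an shRNA against HSF1 or an shRNA against RPA1, with 3 arrays each. The labels do not say whether the 3 arrays of a group come from separate cultures, so every p-value measures only the spread between these samples.

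The deposited values are log2 signals, 1 value per probe set and array, used as deposited. Per the submitters' processing notes they were made with the RMA method in Partek 6.5. The notes do not state the scale; the range and shape of the values were those of a log2 scale, and log2 was inferred from them. The median signal of an array lay between 7.72 and 7.81, and the mean correlation of an array with the others of its group lay between 0.992 and 0.995. The number of arrays, 3 per group, limits the precision.

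The table held 35557 rows. Gene names came from the annotation table given for this array: 21789 rows had 1 gene symbol, 1621 had several and 12147 were not listed, and only rows with 1 symbol were tested. Symbols were checked through gene identifiers against a RefSeq table, which changed 0 of them and did not hold 91 of the identifiers. Of the genes, 999 had more than 1 row, and the row with the highest mean over the 9 arrays stood for the gene, which left 19938 genes. Rows of the same gene passed the threshold in opposite ways for 0 genes under HSF1 shRNA and 3 under RPA1 shRNA. No filter on dim genes was used.

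Tests used R 4.3.3 and limma 3.58.1. A linear model with 1 mean per group was fitted to all 9 arrays (6 residual degrees of freedom per gene, 3.51 prior degrees of freedom), followed by 3 contrasts, empirical Bayes moderation and Benjamini-Hochberg adjustment over the 19938 genes of each contrast. A gene was called at an adjusted p under 0.05, two-sided. An exact test of 3 arrays against 3 cannot give a p below 0.1, so all calls rest on the variance model of limma. Differences are given on the log2 scale ± the standard error from limma with n = 3 arrays per group, and levels as the mean ± SD. The procedure was tested on simulated data with 200 changed genes among 19938, 50 at each of 4 sizes. The sizes were 1.25-fold, 1.5-fold, 2-fold and 3-fold. With the changes placed in the HSF1 shRNA arrays the procedure found 38, 94, 100 and 100% of the 50, with 9 false calls among 175. With the changes in the RPA1 shRNA arrays it found 52, 96, 100 and 100%, with 3 false among 177. Both runs used the same spread per gene, from the fit to all 9 arrays, so they differ only by the random draw. In the data 3210 and 5998 genes passed, far more than in these runs. The Benjamini-Hochberg cut-off on the unadjusted p is looser there, so these shares do not carry over to the data.

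Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, against all other genes, adjusted over 66 tests (22 lists in 3 contrasts). As alternatives, camera was run with the correlation estimated from the residuals, and fry tested whether the list itself differed between the groups without reference to other genes. Members that passed were counted with the adjustment over all genes and again adjusted over the list alone. The 22 lists were heat shock factors; RPA subunits; FACT, SWI/SNF and histone chaperones; cytosolic and nuclear heat shock proteins and co-chaperones; mitochondrial chaperones and proteases; TRiC and prefoldin; proteasome subunits; endoplasmic reticulum (ER) chaperones and the unfolded protein response; DNA replication, mitosis and G2/M, p53 targets, DNA damage response and repair, and replication-dependent histone genes. They further held the type I interferon response, NF-kB and inflammatory genes, extracellular matrix, contractile and SRF or YAP target genes, sterol and fatty acid synthesis, glycolysis and hypoxia, NRF2 and metallothionein genes, ribosome biogenesis, and the shRNA and microRNA machinery. The 7 marker lists named fibroblasts and epithelial, endothelial, macrophage or other blood, muscle, adipocyte and neural cells and were adjusted among themselves. Coverage was lowest for the histone genes, with 14 of 26 members tested. The fibroblast list named S100a4 both by this symbol and by its older name Fsp1, which the synonym table gives for an unrelated gene. Fsp1 was set to S100a4, so the gene counted once and the list held 9 markers.

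The groups, the comparisons, the lists, the named genes and most alternatives were chosen before the data were examined. The rule for named genes took Hsf1 and Rpa1 in every comparison, but Hsf1 was not among the genes tested. For each knockdown it took the 10 called genes with the largest rise and the 10 with the largest fall. Only genes with all knockdown arrays on one side of the control arrays and a higher group mean above the median gene were eligible there. From each list it took up to 4 members with the smallest adjusted p. It also took the 8 genes highest and the 8 lowest in both knockdowns by the smaller of the changes, the 5 called in opposite ways, and the 8 largest differences each way between the knockdowns. Symbols of predicted genes, microRNAs, small nucleolar RNAs and clone names were excepted. Genes named outside the rule are marked as chosen after their values were seen.

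Alternatives were quantile, median and cyclic loess scaling on top of the deposited values; only genes above the median gene; the mean of the rows of a gene; every row as its own unit; empirical Bayes with trend and robust estimation; an unmoderated test; only the 6 arrays compared; the replicate number as a block; array weights; an adjusted p under 0.01; a change of at least 1.5-fold; and each array left out in turn. For set tests the trend alternative was run without the robust option, the unmoderated test was run by ranking its statistics, and the 1.5-fold alternative had no counterpart. The same 3 scalings computed over the tested genes only were added after the data were seen, as were the families of genes in the closing section. No other alternative was run.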

Results

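The series holds 9 arrays of immortalized mouse embryonic fibroblasts, 3 with a scrambled control shRNA, 3 with an shRNA against the heat shock transcription factor HSF1 and 3 with an shRNA against RPA1, the large subunit of the single-stranded DNA binding complex RPA. The study asked whether a complex of HSF1 and RPA controls gene expression, and the knockdowns were compared with the control, with each other and for shared genes. The level of the Hsf1 transcript was not analysed here, so the knockdown of HSF1 was not checked in these arrays.

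Rpa1 (probe set 10388409) read 11.40, 11.42 and 11.41 in the control arrays, 9.42, 9.34 and 9.40 in the RPA1 shRNA arrays and 11.35, 11.33 and 11.30 in the HSF1 shRNA arrays, on the log2 scale. It fell 4.05-fold under RPA1 shRNA (log2 -2.02 ± 0.04, limma adjusted p = 3.5e-08, n = 3 arrays per group). Under HSF1 shRNA its log2 difference was -0.08 ± 0.04 (limma adjusted p = 0.27). Among the other subunits of the complex, Rpa2 fell under RPA1 shRNA (-0.30 ± 0.05, adjusted p = 0.0011), and Rpa3 stood at -0.11 ± 0.10 (adjusted p = 0.43).

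HSF1 shRNA against the control asked which genes respond to HSF1 shRNA in fibroblasts kept at 37 degrees. Sncaip, which encodes the alpha-synuclein partner synphilin, fell 4.78-fold (log2 -2.26 ± 0.10, limma adjusted p = 1.4e-05; 7.27 ± 0.23 against 9.53 ± 0.04, SD, n = 3). Islr (-1.91 ± 0.13, 6.8e-05), the semaphorin receptor gene Plxna4 (-1.70 ± 0.15, 0.00019) and the phosphatase gene Ctdsp2 (-1.63 ± 0.06, 7.6e-06) fell. So did the matrix gene Abi3bp (-1.60 ± 0.11, 6.8e-05) and Ptn, the gene of the growth factor pleiotrophin (-1.58 ± 0.11, 6.8e-05). The cytokine gene Il6 rose 4.74-fold (log2 2.25 ± 0.33, adjusted p = 0.0023), the interferon-induced gene Oas2 by 1.61 ± 0.12 (8.9e-05) and Lipg, which encodes endothelial lipase, by 1.60 ± 0.10 (5.9e-05). Rises also came from Tmem171 (1.59 ± 0.23, 0.0019), the chemokine gene Ccl17 (1.47 ± 0.07, 2.1e-05) and the collagenase gene Mmp13 (1.40 ± 0.11, 0.00012).

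In all, 3210 of 19938 genes (16.1%) passed the limma threshold under HSF1 shRNA, 1971 higher and 1239 lower, and 468 of them changed at least 1.5-fold, 253 up and 215 down; 5697 had an unadjusted p under 0.05. With scalings over the tested genes, added after the data were seen, the split was 1789 higher and 1649 lower (quantile), 1593 and 1717 (median) or 1691 and 1734 (loess). Without HSF1 shRNA array 1 it was 1232 and 1223, so the majority of higher genes depended on the scaling and on this array. The count was 2023 without control array 1, 1953 without control array 3, 2041 without HSF1 shRNA array 3 and 5313 with array weights.

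Interferon genes rose together under HSF1 shRNA: 27 of 33 measured members rose and 0 fell (31 and 0 adjusted over the list alone), with a median log2 difference of 0.75. Rsad2, which encodes the antiviral protein viperin, rose by 1.48 ± 0.16 (limma adjusted p = 0.00045), the nucleic acid sensor gene Zbp1 by 1.19 ± 0.11 (0.00023) and Oas3 by 0.86 ± 0.10 (0.00055). For this list camera gave an adjusted p = 2.4e-16, and adjusted p = 0.27 with an estimated correlation. Of 23 NF-kB and inflammatory genes 12 rose and 1 fell (15 and 2 adjusted over the list alone). NF-kB and inflammatory genes had a median of 0.33 (camera adjusted p = 0.00015, and adjusted p = 0.22 with an estimated correlation). Among them the chemokine genes Ccl20 (1.28 ± 0.14, 0.00057), Ccl2 (0.69 ± 0.08, 0.00071) and Cxcl1 (0.59 ± 0.07, 0.001) rose, as did Tnfaip3, a feedback inhibitor of NF-kB signalling (0.40 ± 0.05, 0.00081).

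Glycolysis and hypoxia genes rose under HSF1 shRNA, 12 of 19 up and 0 down (13 and 1 adjusted over the list alone). Glycolysis genes had a median of 0.33 (camera adjusted p = 0.00033, and adjusted p = 0.41 with an estimated correlation). They included the genes for hexokinase (Hk2, 0.77 ± 0.11, limma adjusted p = 0.0019), phosphofructokinase (Pfkp, 0.62 ± 0.06, 0.00035), pyruvate kinase (Pkm, 0.47 ± 0.05, 0.00055) and lactate dehydrogenase (Ldha, 0.45 ± 0.06, 0.00092). Of 20 ribosome biogenesis genes 6 rose and 0 fell (13 and 0 adjusted over the list alone), among them Rrp9 (0.54 ± 0.07, 0.001) and Bop1 (0.50 ± 0.07, 0.0017). Ribosome biogenesis genes had a median of 0.20 (camera adjusted p = 0.00019, and adjusted p = 0.47 with an estimated correlation). Sterol and fatty acid synthesis genes gave 5 rises and 0 falls among 23 (6 and 0 adjusted over the list alone), with Idi1 (0.53 ± 0.05, 0.00021) and Dhcr7 (0.32 ± 0.05, 0.004), enzymes of the cholesterol pathway. Sterol genes had a median of 0.17 (camera adjusted p = 0.0039, and adjusted p = 0.54 with an estimated correlation). The ribosome biogenesis count was 14 without RPA1 shRNA array 3, and the sterol count 3 without control array 3 or HSF1 shRNA array 3 and 11 without RPA1 shRNA array 3.

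Under HSF1 shRNA 10 of 35 cytosolic and nuclear heat shock proteins and co-chaperones rose and 1 fell (15 and 1 adjusted over the list alone). Heat shock proteins had a median of 0.17 (camera adjusted p = 0.029, and adjusted p = 0.42 with an estimated correlation). The co-chaperone gene Bag1 (0.49 ± 0.05, limma adjusted p = 0.00044), Zfand2a (0.30 ± 0.05, 0.0035) and Hsp90aa1, a cytosolic chaperone gene (0.29 ± 0.05, 0.0043), rose, and Ptges3, a co-chaperone gene, fell (-0.38 ± 0.06, 0.0038). Of 31 proteasome subunits 10 rose and 0 fell (18 and 0 adjusted over the list alone), among them Psmd13 (0.47 ± 0.07, 0.0021) and Psmd12 (0.41 ± 0.07, 0.0039). Proteasome subunits had a median of 0.20 (camera adjusted p = 5.4e-06, and adjusted p = 0.41 with an estimated correlation). Of 24 ER chaperones and unfolded protein response genes 11 rose and 4 fell (13 and 7 adjusted over the list alone), among them Dnajc3 (0.48 ± 0.05, 0.00041), Hyou1 (0.45 ± 0.05, 0.00035) and Creld2 (0.44 ± 0.05, 0.00044). The ER list had a median of 0.15 (camera adjusted p = 0.024, and adjusted p = 0.27 with an estimated correlation). The heat shock list lost its call with quantile scaling (adjusted p = 0.098) and without HSF1 shRNA array 3 (0.07). The ER list lost it with quantile (0.094) or median scaling (0.087), without RPA1 shRNA array 3 (0.061) and with only the 6 arrays compared (0.059). The heat shock count was 6 without control array 1, HSF1 shRNA array 1 or HSF1 shRNA array 3 and 5 without control array 3. The proteasome count was 6 without control array 1, control array 3 or HSF1 shRNA array 3, and 19 without RPA1 shRNA array 3.

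Of 43 DNA replication genes 10 fell, 2 rose and 31 did not pass under HSF1 shRNA (17 falls and 3 rises adjusted over the list alone). DNA replication genes had a median of -0.10 (camera adjusted p = 4.8e-06, and adjusted p = 0.39 with an estimated correlation). The polymerase genes Pold1 (-0.50 ± 0.07, limma adjusted p = 0.0016) and Pole (-0.39 ± 0.06, 0.0037) and the licensing factor gene Cdt1 (-0.38 ± 0.06, 0.0043) fell, while Ccne1, which encodes cyclin E, rose (0.37 ± 0.05, 0.0019). Of 14 histone genes 6 fell and 1 rose (8 and 2 adjusted over the list alone): H1f1 (-0.66 ± 0.07, 0.00045) and H4c4 (-0.35 ± 0.06, 0.0055) fell, and H2bc4 rose (1.22 ± 0.14, 0.00055). Histone genes had a median of -0.24 (camera adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). DNA damage and repair genes gave 2 falls and 1 rise among 25, the same adjusted over the list alone, with Fanci at -0.38 ± 0.05 (0.0018) and the kinase gene Atm at 0.40 ± 0.07 (0.005). DNA damage genes had a median of -0.08 (camera adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation). FACT, SWI/SNF and histone chaperone genes gave 2 falls and 1 rise among 15, the same adjusted over the list alone, with the SWI/SNF genes Smarca2 (-0.50 ± 0.05, 0.00041) and Smarcc2 (-0.25 ± 0.05, 0.012) down. The FACT list had a median of -0.06 (camera adjusted p = 0.016, and adjusted p = 0.48 with an estimated correlation). These last 2 calls were lost among genes above the median gene (adjusted p = 0.067 and 0.077) and with fry (adjusted p = 0.21 and 0.056). Without RPA1 shRNA array 3 the replication list had 18 falls and the DNA damage list 7. The histone count was 3 without HSF1 shRNA array 2 or array 3.

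Extracellular matrix genes moved both ways under HSF1 shRNA, 5 of 29 up and 7 down (5 and 9 adjusted over the list alone). Matrix genes had a median of -0.14 (camera adjusted p = 0.035, and adjusted p = 0.54 with an estimated correlation). Tnc, which encodes tenascin, fell (-1.04 ± 0.07, limma adjusted p = 6.3e-05), and Mmp13, the basement membrane collagen gene Col4a1 (0.38 ± 0.05, 0.0012) and Thbs1 (0.35 ± 0.06, 0.0046) rose. The call was lost with cyclic loess (0.065), the scalings over tested genes (0.16, 0.088 and 0.075), genes above the median gene (0.058), the unmoderated test (0.055), fry (0.3), without HSF1 shRNA array 1 (0.12) and without RPA1 shRNA array 1 (0.052). Falls numbered 2 without control array 1, 4 without control array 2 or HSF1 shRNA array 2, 3 without HSF1 shRNA array 3 and 14 without RPA1 shRNA array 3, and rises 3 without control array 3.

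The other 9 lists did not pass camera under HSF1 shRNA. Heat shock factors gave 1 rise of 4 (camera adjusted p = 0.47), RPA subunits 1 fall of 3 (0.13) and TRiC and prefoldin 3 rises of 14 (0.3), with equal counts adjusted over the list alone. Hsf2 rose (0.23 ± 0.06, limma adjusted p = 0.019), a call lost without control array 1, control array 2 or HSF1 shRNA array 1. Rpa2 fell (-0.17 ± 0.05, limma adjusted p = 0.04). Its call was lost, among other alternatives, with median scaling (log2 -0.15) and without any 1 of the 6 arrays compared (log2 -0.15 to -0.19). The p53 targets gave 6 rises and 2 falls of 25 (camera adjusted p = 0.12), among them Ccng1 (0.43 ± 0.04, limma adjusted p = 3e-04) and Sesn1 (-0.63 ± 0.11, 0.0045). Mitosis and G2/M gave 2 rises and 6 falls of 33 (camera adjusted p = 0.2), mitochondrial chaperones 1 and 1 of 12 (0.6) and the shRNA and microRNA machinery 2 and 1 of 8 (0.38). The last 4 lists had the same counts adjusted over the list alone. Contractile genes gave 4 rises and 3 falls of 22 (6 and 4 adjusted over the list alone; camera adjusted p = 0.96), with Ankrd1 at 0.69 ± 0.05 (limma adjusted p = 6.8e-05), and 7 falls without RPA1 shRNA array 3. NRF2 and metallothionein genes gave 6 rises and 1 fall of 16 (7 and 2 adjusted over the list alone; camera adjusted p = 0.2), with 3 rises without control array 1 or HSF1 shRNA array 3 and 1 without control array 3. Median, mean and test differed in sign for 3 lists: mitochondrial chaperones (median and mean 0.01, test down), mitosis (0.02, -0.03, down) and contractile genes (0.07 and 0.04, down).

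Markers of cell types did not pass as lists under HSF1 shRNA. Of 9 fibroblast markers 1 rose and 2 fell (3 and 2 adjusted over the list alone; median -0.14, camera adjusted p = 0.51): Pdgfra, a growth factor receptor gene, fell (-0.90 ± 0.07, limma adjusted p = 0.00011) and S100a4 rose (1.16 ± 0.18, 0.0027). Epithelial markers gave 1 rise of 8 (5 adjusted over the list alone; camera adjusted p = 0.097), endothelial 1 of 6 (1; 0.6) and macrophage or other blood cells 2 of 8 (4; 0.2), with 0 falls. Muscle markers gave 2 rises of 7 (2 adjusted over the list alone; camera adjusted p = 0.41) and adipocyte markers 1 of 5 (1; 0.54). Neural markers gave 3 rises of 6 (3 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.2), among them Tubb3 (0.52 ± 0.08, limma adjusted p = 0.0024) and Nes (0.49 ± 0.08, 0.003).

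**Figure D1:**
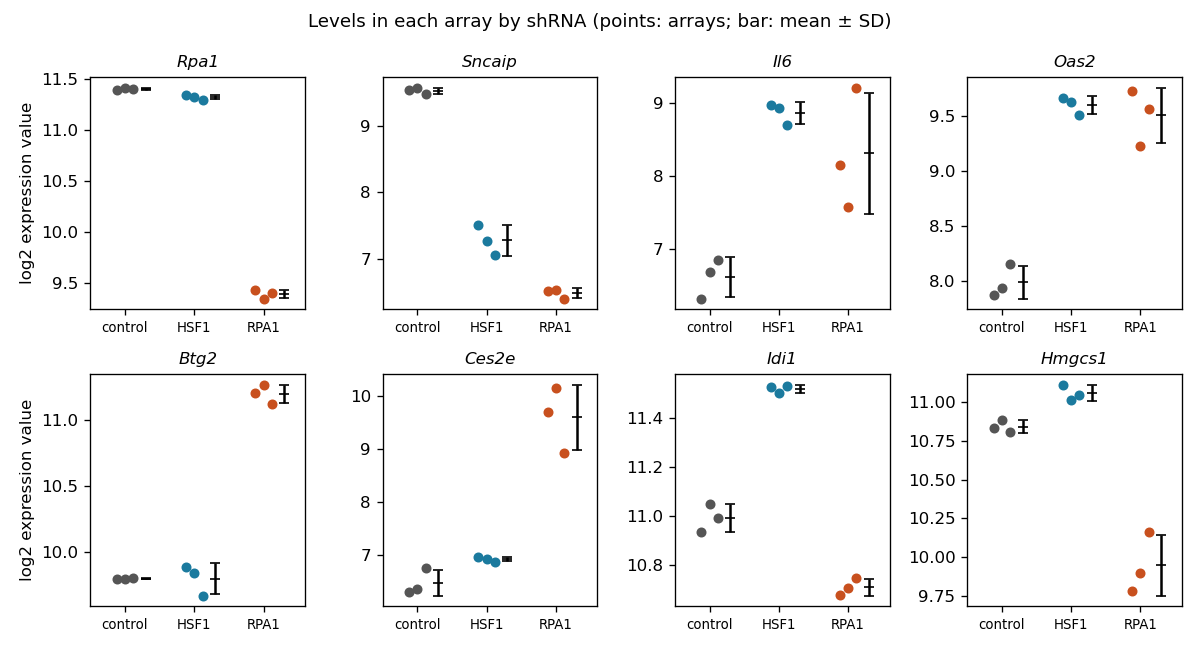
Log2 signal of 8 genes in each of the 9 arrays, with the mean and SD of the 3 arrays of each group.

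RPA1 shRNA against the control asked which genes respond to the RPA1 knockdown. Signal over background was not measured, so folds of falls to low levels may be too small. Sncaip fell 8.27-fold (log2 -3.05 ± 0.10, limma adjusted p = 4.3e-07; 6.48 ± 0.08 against 9.53 ± 0.04, SD, n = 3) and Fmod, which encodes the collagen-binding protein fibromodulin, 7.8-fold (-2.96 ± 0.22, 1.7e-05). Lrrn4 (-2.90 ± 0.16, 4.3e-06), the kinase gene Stk26 (-2.83 ± 0.17, 5.6e-06), Plxna4 (-2.71 ± 0.15, 4.7e-06) and the podocalyxin gene Podxl (-2.42 ± 0.13, 3.8e-06) fell. The carboxylesterase genes Ces2e, Ces2f and Ces2g rose by 3.11 ± 0.25 (2.9e-05), 2.82 ± 0.24 (3.8e-05) and 2.76 ± 0.22 (2.9e-05). Further rises were those of Cd80, a costimulatory ligand of T cells (2.74 ± 0.24, 3.9e-05), the transmembrane glycoprotein gene Gpnmb (2.61 ± 0.21, 2.6e-05), Ccl20 (2.15 ± 0.14, 1.2e-05) and the cornified envelope gene Lce1h (2.06 ± 0.11, 4e-06).

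Under RPA1 shRNA 5998 of 19938 genes (30.1%) passed the limma threshold, 3077 higher and 2921 lower, of which 1411 changed at least 1.5-fold, 681 up and 730 down; 7855 had an unadjusted p under 0.05. The split was 3754 and 2773 with quantile scaling, 2431 and 2704 among genes above the median gene and 3359 and 3854 with every row as its own unit. The count was 9065 with array weights. RPA1 shRNA array 3 stood apart from the other arrays of its group. Among genes at least 2-fold from the control in arrays 1 and 2, its difference from the control was 0.675 times theirs (median). The same ratio for arrays 1 and 2, each over the genes at least 2-fold from the control in the other 2 arrays, was 1.08 and 1.06. Of the 5998 calls 5649 were kept without it.

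p53 targets rose under RPA1 shRNA, 19 of 25 up and 2 down (19 and 3 adjusted over the list alone). The p53 targets had a median of 0.75 (camera adjusted p = 2.4e-08, and adjusted p = 0.22 with an estimated correlation). The receptor gene Eda2r rose by 2.04 ± 0.11 (limma adjusted p = 4.7e-06) and the antiproliferative gene Btg2 by 1.40 ± 0.06 (2.3e-06). The kinase gene Plk2 rose by 1.30 ± 0.05 and the cyclin gene Ccng1 by 1.01 ± 0.04 (both 1.5e-06). Interferon genes rose, 29 of 33 up and 1 down (the same adjusted over the list alone), among them Oas2 (1.51 ± 0.12, 2.7e-05), the RNA sensor regulator gene Dhx58 (1.32 ± 0.12, 4.3e-05) and Zbp1 (1.26 ± 0.11, 4.2e-05). Interferon genes had a median of 0.86 (camera adjusted p = 8e-14, and adjusted p = 0.31 with an estimated correlation). NF-kB and inflammatory genes gave 12 rises and 3 falls of 23 (12 and 4 adjusted over the list alone), with the cytokine genes Csf2 (1.57 ± 0.10, 1.1e-05) and Lif (0.89 ± 0.06, 1.3e-05) and with Tnfaip3 (1.12 ± 0.05, 1.7e-06) up. NF-kB and inflammatory genes had a median of 0.38 (camera adjusted p = 0.00093, and adjusted p = 0.22 with an estimated correlation).

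Contractile and SRF or YAP target genes rose under RPA1 shRNA, 18 of 22 up and 0 down (the same adjusted over the list alone). Contractile genes had a median of 0.55 (camera adjusted p = 1.2e-08, and adjusted p = 0.22 with an estimated correlation). Tagln, a smooth muscle actin-binding protein gene (1.51 ± 0.16, limma adjusted p = 0.00015), Ankrd1 (1.49 ± 0.05, 4.3e-07) and Ccn2, which encodes connective tissue growth factor (1.06 ± 0.11, 1e-04), were among them. Sterol and fatty acid synthesis genes fell, 19 of 23 down and 1 up (the same adjusted over the list alone). Sterol genes had a median of -0.55 (camera adjusted p = 5e-10, and adjusted p = 0.27 with an estimated correlation). Hmgcs1, an early enzyme gene of the mevalonate pathway (-0.89 ± 0.09, 7.8e-05), the squalene synthase gene Fdft1 (-0.75 ± 0.06, 2.7e-05) and Srebf2, the transcription factor gene of this pathway (-0.67 ± 0.06, 3.2e-05), fell. Extracellular matrix genes fell, 17 of 29 down and 4 up (18 and 6 adjusted over the list alone), with the collagen genes Col6a2 (-1.66 ± 0.11, 1.2e-05) and Col6a1 (-1.49 ± 0.14, 5.6e-05) lowest among those named and Thbs1 up (0.57 ± 0.06, 0.00013). Matrix genes had a median of -0.34 (camera adjusted p = 0.0011, and adjusted p = 0.41 with an estimated correlation).

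Fibroblast markers moved with the matrix genes under RPA1 shRNA: 5 of 9 fell and 0 rose (5 and 1 adjusted over the list alone). Fibroblast markers had a median of -0.46 (camera adjusted p = 0.069, and adjusted p = 0.64 with an estimated correlation). The growth factor receptor genes Pdgfra (-1.70 ± 0.07, limma adjusted p = 1.5e-06) and Pdgfrb (-1.06 ± 0.08, 2.7e-05) and the collagen gene Col1a2 (-1.05 ± 0.12, 0.00022) fell. The mean of the list was 10.45, 10.29 and 10.76 in the RPA1 shRNA arrays against 11.06, 11.07 and 11.03 in the control arrays. Of 8 macrophage or other blood cell markers 3 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 0.097), most of all Cd68, a lysosomal glycoprotein gene (2.06 ± 0.17, 2.8e-05). Of 6 neural markers 4 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.2), with Nes at 0.81 ± 0.08 (6.6e-05). Epithelial markers gave 1 rise of 8 (Krt14, 0.61 ± 0.07, 0.00019; camera adjusted p = 0.54), and endothelial 1 rise of 6 (0 adjusted over the list alone; 0.54). Muscle markers gave 2 rises of 7 (camera adjusted p = 0.38) and adipocyte markers 1 fall of 5 (0.67), these and the epithelial list with equal counts adjusted over the list alone.

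Histone genes fell under RPA1 shRNA, 9 of 14 down and 1 up (the same adjusted over the list alone). Histone genes had a median of -0.46 (camera adjusted p = 0.00015, and adjusted p = 0.22 with an estimated correlation). H1f1 (-1.29 ± 0.07, limma adjusted p = 4.7e-06) and H1f5 (-1.10 ± 0.10, 5.7e-05), linker histone genes, fell, and H2bc4 rose (1.79 ± 0.14, 2.3e-05). Mitosis and G2/M genes gave 9 falls and 1 rise of 33 (the same adjusted over the list alone), with the kinetochore gene Cenpf (-0.48 ± 0.06, 0.00038) and the mitotic kinesin gene Kif11 (-0.45 ± 0.06, 0.00047) down. Mitosis genes had a median of -0.05 (camera adjusted p = 0.0039, and adjusted p = 0.41 with an estimated correlation). DNA replication genes gave 13 falls and 7 rises of 43 (19 and 7 adjusted over the list alone): Gins4 (-0.54 ± 0.06, 0.00012) and Pold1 (-0.45 ± 0.07, 0.001) fell and Ccne1 rose (1.28 ± 0.05, 1.5e-06). DNA replication genes had a median of -0.11 (camera adjusted p = 0.031, and adjusted p = 0.6 with an estimated correlation). RPA subunits gave 2 falls and 0 rises of 3 (the same adjusted over the list alone). RPA subunits had a median of -0.30 (camera adjusted p = 0.0042, and adjusted p = 0.22 with an estimated correlation). This list holds the targeted gene Rpa1, so its call in part restates the knockdown. The mitosis call was lost among genes above the median gene (0.058). The replication call was lost there (0.21), with cyclic loess (0.061), with quantile (0.13) or loess scaling (0.063) over the tested genes, with array weights (0.073), with fry (0.17) and without RPA1 shRNA array 3 (0.16), and replication falls numbered 8 without control array 2.

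Ribosome biogenesis genes rose under RPA1 shRNA, 13 of 20 up and 0 down (14 and 0 adjusted over the list alone), with Rrp9 (0.95 ± 0.07, limma adjusted p = 1.7e-05), the transcription factor gene Myc (0.84 ± 0.07, 3.6e-05) and the fibrillarin gene Fbl (0.44 ± 0.05, 0.00015). Ribosome biogenesis genes had a median of 0.30 (camera adjusted p = 9.7e-07, and adjusted p = 0.41 with an estimated correlation). Of 35 heat shock proteins and co-chaperones 13 rose and 3 fell (the same adjusted over the list alone), among them the small heat shock protein gene Cryab (0.88 ± 0.08, 4.7e-05), Zfand2a (0.58 ± 0.05, 3.5e-05) and Dnaja4 (0.56 ± 0.06, 0.00014). Heat shock proteins had a median of 0.10 (camera adjusted p = 0.027, and adjusted p = 0.41 with an estimated correlation). Of 31 proteasome subunits 12 rose and 1 fell (13 and 1 adjusted over the list alone), with Psmc4 at 0.31 ± 0.05 (0.00088). Proteasome subunits had a median of 0.12 (camera adjusted p = 0.013, and adjusted p = 0.6 with an estimated correlation). The heat shock call was lost with quantile scaling (0.056) and without RPA1 shRNA array 3 (0.099), and the proteasome call without that array (0.26) and with array weights (0.2); heat shock rises numbered 8 without control array 3.

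The other 9 lists did not pass camera under RPA1 shRNA. ER chaperones and unfolded protein response genes gave 12 rises and 6 falls of 24 (12 and 8 adjusted over the list alone; camera adjusted p = 0.33), among them the stress-induced transcription factor gene Atf3 (1.23 ± 0.07, limma adjusted p = 4e-06) and Xbp1 (-0.52 ± 0.06, 0.00023). NRF2 and metallothionein genes gave 6 and 3 of 16 (camera adjusted p = 0.45), with the heme oxygenase gene Hmox1 up (1.00 ± 0.15, 0.00085) and the glutathione transferase gene Gstm1 down (-1.02 ± 0.09, 3.9e-05). DNA damage and repair genes gave 2 rises and 5 falls of 25 (camera adjusted p = 0.24), with Brca2 (-0.74 ± 0.15, 0.0049) and Trp53bp1 (-0.44 ± 0.05, 2e-04) down. FACT, SWI/SNF and histone chaperones gave 1 and 3 of 15 (0.53), with Smarca2 down (-0.69 ± 0.05, 2.3e-05). TRiC and prefoldin gave 3 and 1 of 14 (0.38) and heat shock factors 0 and 0 of 4 (0.48), and these 5 lists had the same counts adjusted over the list alone. Mitochondrial chaperones gave 4 rises of 12 (6 adjusted over the list alone; camera adjusted p = 0.16), and the shRNA and microRNA machinery 4 rises and 3 falls of 8 (5 and 3; 0.47). Glycolysis and hypoxia genes gave 5 rises and 2 falls of 19 (6 and 3 adjusted over the list alone; camera adjusted p = 0.88), with 3 rises without control array 1. Only here did the median (-0.01) and the test (up) differ in sign.

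**Figure D2:**
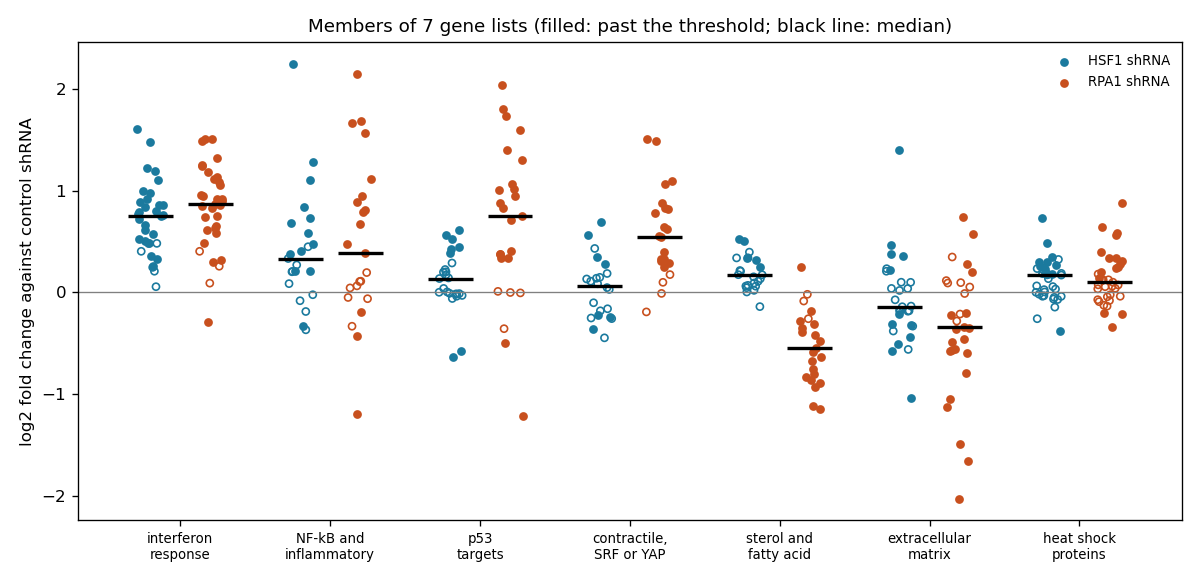
Log2 difference from the control of each member of 7 gene lists in the HSF1 and RPA1 knockdowns, filled where it passed the limma threshold, with the list median as a black line. Each of these medians kept its sign under every scaling, and for the contractile genes under HSF1 shRNA the median and the test differed in sign.

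The direct comparison asked which genes responded differently to the knockdowns. Rpa1 was higher under HSF1 shRNA than under RPA1 shRNA by 1.94 ± 0.04 (limma adjusted p = 5.2e-08). Pla2g7, which encodes a phospholipase that cleaves platelet-activating factor (1.76 ± 0.23, 0.00078), Gpm6a (1.67 ± 0.11, 5.3e-05), Lipg (1.53 ± 0.10, 5.2e-05) and the aldo-keto reductase gene Akr1c14 (1.53 ± 0.11, 6.1e-05) were also higher. Ces2e (-2.66 ± 0.25, 0.00018), Tbc1d8 (-2.25 ± 0.28, 6e-04), Cd80 (-2.13 ± 0.24, 0.00037), the solute carrier gene Slc4a11 (-1.92 ± 0.13, 6.1e-05) and Ubn1, a gene of the HIRA histone chaperone complex (-1.76 ± 0.09, 2.9e-05), were lower. In all, 4863 of 19938 genes (24.4%) passed the limma threshold, 2928 higher and 1935 lower under HSF1 shRNA, and 912 differed at least 1.5-fold, 521 and 391; 7031 had an unadjusted p under 0.05. With the added scalings over the tested genes the split was 2669 and 2520 (quantile), 2426 and 2672 (median) or 2645 and 2503 (loess). The count was 3228 without RPA1 shRNA array 1 and 7926 with array weights.

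Sterol and fatty acid synthesis genes differed most between the knockdowns: 20 of 23 were higher and 0 lower under HSF1 shRNA (the same adjusted over the list alone). Sterol genes had a median of 0.76 (camera adjusted p = 4.1e-14, and adjusted p = 0.22 with an estimated correlation). Hmgcs1 differed by 1.11 ± 0.09 (limma adjusted p = 8.5e-05), Idi1 by 0.81 ± 0.05 (3.8e-05) and Srebf2 by 0.74 ± 0.06 (7.7e-05). Contractile genes were lower under HSF1 shRNA, 17 of 22 lower and 0 higher (18 and 0 adjusted over the list alone), with Tagln at -1.69 ± 0.16 (0.00021) and the focal adhesion gene Vcl at -0.57 ± 0.06 (0.00026). Contractile genes had a median of -0.49 (camera adjusted p = 1.7e-12, and adjusted p = 0.22 with an estimated correlation). Of 25 p53 targets 17 were lower and 1 higher (18 and 2 adjusted over the list alone), with Btg2 at -1.40 ± 0.06 (2e-05) and Mdm2, which encodes the ubiquitin ligase of p53, at -1.28 ± 0.10 (7.7e-05). The p53 targets had a median of -0.51 (camera adjusted p = 4.5e-11, and adjusted p = 0.22 with an estimated correlation).

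Glycolysis and hypoxia genes were higher under HSF1 shRNA than under RPA1 shRNA, 10 of 19 with 0 lower (13 and 0 adjusted over the list alone), among them Pdk1 (0.75 ± 0.12, limma adjusted p = 0.0019) and Pfkl (0.72 ± 0.12, 0.0031). Glycolysis genes had a median of 0.22 (camera adjusted p = 0.00031, and adjusted p = 0.41 with an estimated correlation). Of 29 extracellular matrix genes 12 were higher and 2 lower (15 and 2 adjusted over the list alone), with the crosslinking enzyme gene Lox at 1.47 ± 0.27 (0.0037) and Col6a1 at 1.16 ± 0.14 (0.00051). Matrix genes had a median of 0.25 (camera adjusted p = 0.0035, and adjusted p = 0.41 with an estimated correlation). Fibroblast markers moved with them, 7 of 9 higher and 0 lower (the same adjusted over the list alone), with Pdgfrb at 0.86 ± 0.08 (0.00022) and Pdgfra at 0.80 ± 0.07 (0.00014). Fibroblast markers had a median of 0.54 (camera adjusted p = 0.0055, and adjusted p = 0.53 with an estimated correlation). Of 14 histone genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone), with H1f5 at 0.71 ± 0.10 (0.0012). Histone genes had a median of 0.22 (camera adjusted p = 0.0035, and adjusted p = 0.3 with an estimated correlation). The histone call was lost among genes above the median gene (0.056). The glycolysis count was 6 without RPA1 shRNA array 1, the fibroblast count 3 without HSF1 shRNA array 1, RPA1 shRNA array 1 or RPA1 shRNA array 2. Higher histone genes numbered 3 without HSF1 shRNA array 1, HSF1 shRNA array 2 or RPA1 shRNA array 1.

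Of 20 ribosome biogenesis genes 7 were lower and 0 higher under HSF1 shRNA than under RPA1 shRNA (8 and 0 adjusted over the list alone), with Myc at -0.50 ± 0.07 (limma adjusted p = 0.0012). Ribosome biogenesis genes had a median of -0.11 (camera adjusted p = 0.00093, and adjusted p = 0.52 with an estimated correlation). The call was lost without RPA1 shRNA array 3 (0.11) and with fry (0.06). Mitochondrial chaperones gave 4 lower and 0 higher of 12 (the same adjusted over the list alone), with Hspe1 at -0.35 ± 0.07 (0.0045). Mitochondrial chaperones had a median of -0.12 (camera adjusted p = 0.029, and adjusted p = 0.46 with an estimated correlation). This call was lost without RPA1 shRNA array 3 (0.12), among genes above the median gene (0.067) and with array weights (0.16). Interferon genes gave 5 lower and 1 higher of 33 (4 and 1 adjusted over the list alone), with the antigen transporter gene Tap1 at -0.86 ± 0.15 (0.0028) and Ifit2 at 0.65 ± 0.06 (0.00021). Interferon genes had a median of -0.07 (camera adjusted p = 0.031, and adjusted p = 0.7 with an estimated correlation). That call was lost with cyclic loess (0.051), quantile (0.05) and median scaling (0.092) over the tested genes, fry (0.52), without HSF1 shRNA array 3 (0.06) and without RPA1 shRNA array 1 (0.58). The lower interferon genes numbered 3 without control array 2 or HSF1 shRNA array 1 and 2 without HSF1 shRNA array 2, HSF1 shRNA array 3 or RPA1 shRNA array 1. Mitosis and G2/M genes gave 8 higher and 2 lower of 33 (10 and 2 adjusted over the list alone). Mitosis genes had a median of 0.10 (camera adjusted p = 0.046, and adjusted p = 0.54 with an estimated correlation). Their call was lost under all 6 scalings (0.079 to 0.15), among genes above the median gene (0.19), with array weights (0.062) and without HSF1 shRNA array 1 (0.083) or array 3 (0.076) or RPA1 shRNA array 1 (0.062), array 2 (0.064) or array 3 (0.054). The higher mitosis genes numbered 5 without HSF1 shRNA array 1 or RPA1 shRNA array 2, 4 without RPA1 shRNA array 1 and 13 without RPA1 shRNA array 3. RPA subunits, which hold the targeted gene Rpa1, gave 1 higher and 0 lower of 3 (2 and 0 adjusted over the list alone). RPA subunits had a median of 0.14 (camera adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation), a call lost among genes above the median gene (0.058) and without RPA1 shRNA array 3 (0.087).

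The other 11 lists did not pass camera in the direct comparison. NF-kB and inflammatory genes gave 6 higher and 7 lower of 23 under HSF1 shRNA (6 and 9 adjusted over the list alone; camera adjusted p = 0.19), with Csf2 at -1.09 ± 0.10 (limma adjusted p = 0.00018) and Tnfaip3 at -0.71 ± 0.05 (6.1e-05). Heat shock proteins and co-chaperones gave 6 and 7 of 35 (9 and 9 adjusted over the list alone; camera adjusted p = 0.33), and 10 higher without RPA1 shRNA array 3. Among them were Cryab at -0.65 ± 0.08 (0.00055) and Hspa2 at 0.51 ± 0.07 (0.00086). DNA replication gave 6 and 7 of 43 (camera adjusted p = 0.055), with Ccne1 at -0.91 ± 0.05 (3.5e-05). The ER list gave 7 and 4 of 24 (0.2), DNA damage 4 and 2 of 25 (0.45) and the shRNA and microRNA machinery 3 and 2 of 8 (0.77), these 4 lists with the same counts adjusted over the list alone. Replication genes numbered 3 higher without HSF1 shRNA array 1, RPA1 shRNA array 1 or RPA1 shRNA array 2. Lower replication genes numbered 3 without HSF1 shRNA array 2, HSF1 shRNA array 3 or RPA1 shRNA array 2, 4 without RPA1 shRNA array 1 and 14 without RPA1 shRNA array 3. The ER list had 4 higher without HSF1 shRNA array 1, HSF1 shRNA array 2 or RPA1 shRNA array 1. NRF2 genes gave 5 and 3 of 16 (5 and 5 adjusted over the list alone; 0.96), and proteasome subunits 4 and 0 of 31 (0 and 0; 0.26). Without RPA1 shRNA array 3 the proteasome list had 13 higher and 0 lower and the DNA damage list 9 lower. Proteasome subunits had 0 higher without HSF1 shRNA array 1, RPA1 shRNA array 1 or RPA1 shRNA array 2. TRiC and prefoldin gave 3 and 1 of 14 (4 and 1 adjusted over the list alone; camera adjusted p = 0.95), FACT, SWI/SNF and histone chaperones 1 and 2 of 15 (0 and 0; 0.28) and heat shock factors 0 and 0 of 4 (2 and 1; 0.95). Median, mean and test differed in sign for 5 lists: heat shock factors (0.01, -0.04, down), DNA damage (-0.08, 0.00, down), NF-kB (0.04, -0.07, down), NRF2 (-0.04, 0.04, down) and the shRNA machinery (-0.06, 0.03, down).

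Other marker lists did not pass in the direct comparison. Epithelial markers gave 3 higher and 1 lower of 8 under HSF1 shRNA (camera adjusted p = 0.63), endothelial 0 and 0 of 6 (0.69) and macrophage or other blood cell markers 0 and 1 of 8 (0.36). Muscle markers gave 0 and 1 of 7 (camera adjusted p = 0.69) and neural markers 0 and 1 of 6 (0.6), these 5 lists with equal counts adjusted over the list alone. Adipocyte markers gave 2 and 0 of 5 (2 and 1 adjusted over the list alone; camera adjusted p = 0.46). Cd68 was the macrophage marker that differed (-1.58 ± 0.17, limma adjusted p = 0.00029), and Fabp4, a fatty acid binding protein gene, an adipocyte marker (0.58 ± 0.08, 0.0012).

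Over all lists, camera with the preset correlation called 13, 13 and 11 of 22 lists in the HSF1, RPA1 and direct comparisons, and fry called 14, 15 and 11. With an estimated correlation camera called 0, 0 and 0 (2, 5 and 4 at an unadjusted p under 0.05). No list call held with an estimated correlation, so these calls rest on the preset form of camera and, for fry, on a test of the list by itself. The size of the estimate does not by itself account for the loss. The ER list under HSF1 shRNA had an estimate of 0.013, near the preset 0.01, and its camera adjusted p went from 0.024 to 0.27. RPA subunits under RPA1 shRNA had an estimate of -0.12 and went from 0.0042 to 0.22.

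Genes shared by the knockdowns bear on whether HSF1 and RPA1 act on the same genes. Of the 3210 genes called under HSF1 shRNA 2002 (62.4%) were called in the same direction under RPA1 shRNA, 1150 higher and 852 lower in both, against 486 for independent lists. This split turned to 1008 higher and 1105 lower with median scaling over the tested genes and to 1048 and 1131 with loess over them. Without HSF1 shRNA array 1 it was 795 and 848, so the direction of the split was left open. Sncaip, Islr, Plxna4, Lrrn4, Ptn, Abi3bp, Stk26 and the transporter gene Slc44a5 were the 8 lowest in both knockdowns, with Slc44a5 at -1.63 ± 0.11 and -1.97 ± 0.11 (limma adjusted p = 6.4e-05 and 4e-06). The 8 highest were Il6 (1.69 ± 0.33 under RPA1 shRNA, 0.0039), Oas2, Tmem171, Rsad2, Ccl17, Ccl20, U90926 and the complement receptor gene C3ar1 (1.81 ± 0.14 and 1.46 ± 0.14, 0.00012 and 8.4e-05). The change was larger under RPA1 shRNA for 1336 of the 2002 genes, and the direct test called 666 of the 2002 different. The shared count was 1317 without control array 1, 1285 without control array 3, 1299 without HSF1 shRNA array 3 and 3150 with array weights.

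Opposite calls numbered 124, of which 70 were higher under HSF1 shRNA and lower under RPA1 shRNA and 54 the reverse, against 480 for independent lists. Slc35g1 fell under HSF1 shRNA and rose under RPA1 shRNA (-0.67 ± 0.08 and 0.57 ± 0.08, limma adjusted p = 0.00061 and 0.00048), as did the focal adhesion gene Tgfb1i1 (-0.52 ± 0.10 and 0.51 ± 0.10, 0.0065 and 0.0033). Tbc1d8b (0.55 ± 0.08 and -0.65 ± 0.08, 0.0027 and 0.00039) and the tubulin gene Tubb4a (0.64 ± 0.13 and -0.60 ± 0.13, 0.0087 and 0.0059) did the reverse. The split was 66 and 88 with cyclic loess, and 67 and 97, 53 and 103 or 63 and 100 with quantile, median or loess scaling over the tested genes. Opposite calls numbered 44, 42 and 39 without control arrays 1, 2 and 3, then 80, 65 and 68 without HSF1 shRNA arrays 1, 2 and 3, 76 without RPA1 shRNA array 1 and 554 without RPA1 shRNA array 3. They numbered 203 with only the 6 arrays of each comparison and 609 with array weights.

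Both comparisons used the same 3 control arrays, which alone makes their differences move together. Across genes the correlation of the changes was 0.582, against a mean of 0.50 (0.483 to 0.520) in 100 simulated data sets without any knockdown effect, and the share of genes with the same sign was 68.4% against 66.7%. The covariance was 0.0414, against 0.00356 and at most 0.00375 in the simulations. Without RPA1 shRNA array 3 the correlation was 0.5023 and the covariance 0.03939. The value 0.5023 lies inside the range simulated for the 9 arrays, but no simulation was run with that array left out. Whether the correlation exceeds what shared controls give in that setting was therefore not tested. The covariance that shared controls give comes from the 3 control arrays, which were all kept. The covariance of 0.03939 lay above the highest simulated value, 0.00375. It argues against independent spread of the control arrays as the only source there. The simulations drew each gene independently, so their ranges leave out variation shared by genes. Genes are not replicates, so no p-value was computed for these values.

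**Figure D3:**
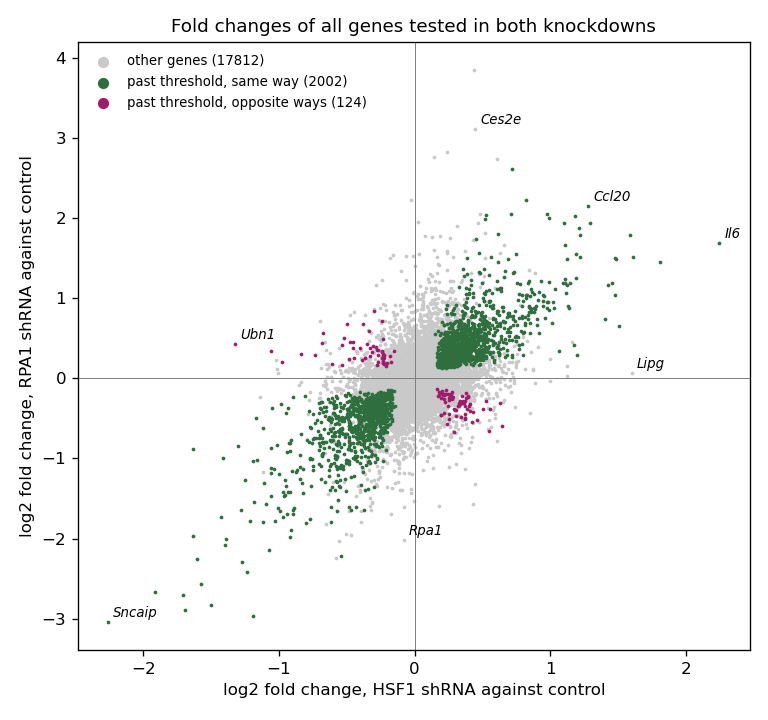
Log2 difference from the control of each gene under HSF1 and RPA1 shRNA, with the 2002 genes called the same way and the 124 called opposite ways marked.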

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

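The tests of explanations in this part were chosen after the results were seen; the comparison of the knockdowns with each other was planned. The following results were picked out because they differed between the knockdowns in the direct test: 4863 genes, and the lists with median log2 differences (HSF1 shRNA minus RPA1 shRNA) of 0.76 for sterol synthesis, 0.54 for fibroblast markers, 0.25 for extracellular matrix, 0.22 for glycolysis and 0.22 for histone genes. Smaller ones were 0.14 for RPA subunits, which hold the targeted gene Rpa1, and 0.10 for mitosis. On the other side stood p53 targets (-0.51), contractile genes (-0.49), mitochondrial chaperones (-0.12), ribosome biogenesis (-0.11) and interferon genes (-0.07).

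RPA1 shRNA array 3 lay closer to the control arrays than the other arrays of its group, with changes 0.675 times as large among 505 genes at least 2-fold from the control in arrays 1 and 2. If control RNA had been mixed in, these genes gave a share of 32.6%, and Rpa1 would have read 10.38 in that array. It read 9.40, a gap of 0.98 against a residual SD of 0.05, which speaks against mixing. A weaker fall of Rpa1 mRNA was not seen either, since the fall in array 3 was 0.991 times that in arrays 1 and 2. A difference in the timing of the response or in the RPA1 protein was not tested and stays possible. Over all rows RPA1 shRNA array 3 correlated by 0.99258 with HSF1 shRNA array 2. Its correlation with RPA1 shRNA arrays 1 and 2 was 0.99249 and 0.99217, so it was as near to that array of the other knockdown. With HSF1 shRNA arrays 1 and 3 it was 0.99006 and 0.99154, and with the control arrays at most 0.98913.

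Interferon genes were higher in both knockdowns than in the control. Spread between arrays alone was tested by all 84 ways of choosing 3 control arrays: the difference of 0.78 between the list means was the largest (exact permutation p = 0.0119, the smallest possible). The list means were 10.24 to 10.61 in the knockdown arrays and 9.44 to 9.71 in the control arrays. The list was picked from 22 after its rise was seen, and this p was not adjusted for that choice. It therefore cannot exclude spread between arrays. A response to the shRNA vectors apart from their targets could not be told from an effect of the targets, because each target had 1 shRNA; the median difference between the knockdowns was -0.07. Whether the scrambled shRNA differs from the other vectors in this respect was not tested.

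The knockdowns moved genes in the same direction more often than in opposite directions. Spread between the shared control arrays gave a covariance of 0.00356 in simulations, and the observed covariance was 11.6 times that, above every simulated value. The simulations drew each gene independently, so variation shared by genes could widen that range. Spread that is independent between genes therefore accounts for only part of the common change. A shift common to all control arrays would also enter both comparisons. The simulations held no such shift, so they cannot exclude the shared control group as a source. Whether the rest comes from variation shared by genes, from such a shift or from a complex of the proteins was not tested. Separate effects on the same genes and effects of the vectors were not tested either.

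Regrouping the 6 arrays of each comparison could not give a share under 0.05, since only 10 splits exist. In each comparison 1 of 10 splits, the real one, reached the observed count in limma (3210, 5998 and 4863 genes), and the highest other count was 0 in each; at an unadjusted p under 0.05 the highest other counts were 701, 1548 and 2072. Every other split put arrays of both groups on each side. Real differences then enter the spread and lower the count, so the 0 does not measure what chance alone gives.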

How the results depend on the processing

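The scalings over the tested genes were added after the data were seen; all other alternatives were planned. No call on a named gene turned in direction, but 1 of the 5998 RPA1 calls turned with the mean of a gene's values. Averaging can turn a call only where rows of the same gene changed in opposite ways. Under RPA1 shRNA 3 genes had rows called in opposite ways, and whether the turned gene is among them was not checked. Rpa1 kept its fall under RPA1 shRNA. Of 349 named gene results past the threshold 299 kept their call and direction under every alternative run for them and 50 lost the call under at least 1, 2 of them only with the unmoderated test. The 2 stricter thresholds and every row as its own unit were not run for named genes, and the filter at the median gene only for those it kept. Counts below are given in the order HSF1 shRNA, RPA1 shRNA, HSF1 against RPA1 shRNA, shared and opposite genes (3210, 5998, 4863, 2002 and 124 as first given). An adjusted p under 0.01 gave 1451, 3817, 2582, 929 and 24, and at least 1.5-fold gave 468, 1411, 912, 273 and 1, as stricter thresholds can only lower them. Every row as its own unit gave 3455, 7213, 4616, 2114 and 95. Array weights gave 5313, 9065, 7926, 3150 and 609; RPA1 shRNA array 3 had the lowest weight (0.21), leaving it out also raised the counts, and the cause was not tested. Only the 6 arrays of each comparison gave 4523, 5101, 3296, 2350 and 203. The group means compared stay the same there, and only the estimate of the spread and its degrees of freedom can differ. The HSF1 count also rose, to 4696, without RPA1 shRNA array 3, which is not part of that comparison. Leaving out 1 array gave 1953 to 4696, 4642 to 7245, 3228 to 6539, 1285 to 2557 and 39 to 554 genes, the low ends with fewer arrays to estimate the spread and the high ends without RPA1 shRNA array 3. The correlation of the knockdowns, 0.582, ranged from 0.5023 without RPA1 shRNA array 3 to 0.6252 without RPA1 shRNA array 2, and the cause was not tested. Of 66 set tests 37 passed; 0 passed in camera with an estimated correlation (2, 5 and 4 in the comparisons at an unadjusted p under 0.05), and the cause was not tested. With fry 40 passed.

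The replicate number as a block gave 2799, 5692, 4414, 1757 and 94 genes (opposite genes 43 and 51) and 38 set tests, and 16 calls on named genes were lost, Rpa2 under HSF1 shRNA among them; residuals of arrays with the same number correlated by -0.159 to 0.0933, and 4 of 9 arrays correlated best with their own number. List medians changed sign under some scaling only for lists that did not pass: heat shock factors, TRiC and NF-kB genes in the direct comparison, mitochondrial chaperones and mitosis under HSF1 shRNA, glycolysis under RPA1 shRNA, muscle markers under HSF1 shRNA and in the direct comparison, and adipocyte markers under RPA1 shRNA. List counts under 5 often moved by over 1.5 times when 1 array was left out, and not all of these moves are given. Of the 3210 HSF1 calls all were kept without RPA1 shRNA array 3, as were 4670 of the 4863 in the direct comparison. Signal over background was not measured, which limits what the dim genes show; among genes above the median gene the counts were 3179, 5135, 4462, 2008 and 184, and 28 set tests passed.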

Other observations

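The families and genes of this part were chosen after their values were seen. Among 27 families scanned in 81 tests, 22 passed camera with the preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05); arrays were not left out for these tests. The smallest camera adjusted p was that of 67 cytosolic ribosomal protein genes under HSF1 shRNA (4.7e-05, and adjusted p = 0.61 with an estimated correlation). Of these 1 rose and 9 fell (median -0.07). Under RPA1 shRNA 2 rose and 13 fell (median -0.08, camera adjusted p = 0.0089, and adjusted p = 0.76 with an estimated correlation). Of 21 V-ATPase subunit genes, which encode the proton pump of lysosomes, 8 rose and 1 fell under HSF1 shRNA and 12 rose and 0 fell under RPA1 shRNA. Their medians were 0.22 (camera adjusted p = 0.012, and adjusted p = 0.66 with an estimated correlation) and 0.27 (0.00076, and adjusted p = 0.61 with an estimated correlation). Atp6v1c1 rose by 0.48 ± 0.07 and 0.80 ± 0.07 (limma adjusted p = 0.0017 and 3.8e-05) and Atp6v1h by 0.41 ± 0.07 and 0.77 ± 0.07 (0.0035 and 4.1e-05). The isoform gene Atp6v0a1 fell under HSF1 shRNA (-1.01 ± 0.08, 9.6e-05; 0.12 ± 0.08, 0.3 under RPA1 shRNA), while Atp6v0a4 rose in both knockdowns (1.06 ± 0.09 and 0.35 ± 0.09, 0.00012 and 0.013). Of 32 Ccl and Cxcl chemokine genes 14 rose and 1 fell under HSF1 shRNA and 13 rose and 3 fell under RPA1 shRNA. Their medians were 0.26 (camera adjusted p = 0.0014, and adjusted p = 0.6 with an estimated correlation) and 0.06 (0.043, and adjusted p = 0.61 with an estimated correlation). Cxcl9 (0.91 ± 0.06 and 0.57 ± 0.06, limma adjusted p = 6.8e-05 and 0.00018) and Cxcl10 (0.86 ± 0.14 and 1.12 ± 0.14, 0.0035 and 0.00031), chemokine genes induced by interferon, rose, and Cxcl12, a stromal chemokine gene, fell (-1.06 ± 0.12 and -1.47 ± 0.12, 0.00057 and 3e-05).

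Of 42 genes with symbols that begin with Kif, which include a pseudogene and the kinesin partner genes Kifap3 and Kifbp, 15 fell, these 2 among them, and 3 rose under RPA1 shRNA (median -0.13, camera adjusted p = 0.0067, and adjusted p = 0.66 with an estimated correlation). Kif26b (-1.35 ± 0.16, limma adjusted p = 0.00025), Kif21b (-0.96 ± 0.07, 2.2e-05) and the mitotic gene Kif18a (-0.84 ± 0.10, 0.00018) fell, and the neuronal gene Kif1a rose (0.89 ± 0.08, 6.7e-05). Carboxylesterase genes gave 5 rises of 16 under RPA1 shRNA (camera adjusted p = 0.15), with Ces2b at 1.10 ± 0.17 (limma adjusted p = 0.00099) beside Ces2e, Ces2f and Ces2g; whether these neighbours share probes was not tested. Of 9 genes known as targets of HSF1 after heat shock 2 passed under HSF1 shRNA. Hsp90aa1 rose (0.29 ± 0.05, limma adjusted p = 0.0043), and Hsph1 stood at 0.35 ± 0.10 (0.049), past the threshold in 8 of the 21 alternatives run for it and not past it in 13. The others stood at 0.06 (Hspa1a, 0.72), -0.07 (Hspa8, 0.34), -0.26 (Hspb1, 0.17), 0.12 (Hspd1, 0.27), -0.16 (Hspe1, 0.13), 0.00 (Dnajb1, 0.996) and 0.17 (Bag3, 0.24).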
